A study of Mus musculus with 6 samples.

How the data were processed

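The labels describe 6 libraries of lateral amygdala RNA in 3 groups of 2, named control, scrambled siRNA and Baf53b siRNA. Per the labels' protocols, messenger RNA was selected with oligo-dT beads from total RNA, a stranded library kit was used, and fragments were sequenced from both ends. Per the submitters' processing notes, bcl2fastq 2.19.1.403, TopHat2 2.1.1 and Cufflinks 2.2.1 were used with the mouse build mm10. The annotation release and the settings are not given in the sources used here.

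The authors deposited 1 table per library with FPKM per gene, the lower and upper bounds of a confidence interval on the FPKM, and a status, per the file headers. FPKM is relative to gene length and to the fragments of the library, so a gene that takes many fragments lowers the others. Each table held 50383 distinct gene IDs and 92 rows of synthetic spike-in RNA, which the labels do not mention. For 48 gene IDs several rows were summed. With GENCODE M21, which uses the same build, 50160 IDs matched and 46627 of these had an identical start and end. Annotations of gene type come from there, and coordinates are those of the deposited tables. There were 4 genes with a failed estimate in a control library, which were left out.

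Read counts were not used here, so the depth of a gene was estimated from its deposited interval, taking its half-width as 2 standard errors of a count. This gave 8.93 M and 10.3 M fragments behind the genes in control, 6.43 M and 10.7 M in scrambled siRNA and 7.66 M and 8.52 M in Baf53b siRNA. The median gene at 1 FPKM or more had between 171 and 306 fragments per library, and Actl6b had between 444 and 623. These estimates cover counting error only. Genes of the mitochondrial chromosome made up 19.4% and 29.5% of the FPKM sum in control, 15.0% and 26.9% in scrambled siRNA and 19.3% and 22.8% in Baf53b siRNA.

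Values were taken as log2(FPKM + 1) with a pseudocount of 1. Genes with a mean FPKM of at least 1 over the 6 libraries were kept, small RNA genes of the microRNA, small nucleolar, small Cajal body, small nuclear, vault, ribosomal (nuclear) and mitochondrial transfer RNA types (360 at that level) were left out, other short RNA such as the Y RNA gene Rny3 was kept, and 14657 genes were tested. Group means were fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (eBayes with trend, without robust), which pools the spread over groups (3 residual degrees of freedom, prior 3.99), and the 3 comparisons were two-sided with Benjamini-Hochberg adjustment at 0.05. Actl6b was also compared by exact permutation tests over libraries. The 34 gene lists were fixed before the data were examined, and cover the BAF complex, neuronal functions, cell types and neighbouring regions a dissection could hold, reactions to injection, and RNA and metabolic state. Lists were tested with limma's camera (preset inter-gene correlation 0.01, at least 5 tested members). Camera with an estimated correlation and fry were run beside it, and every test was adjusted over the lists of a comparison. Camera with an estimated correlation also uses only the 3 residual degrees of freedom, so its larger p-values do not come from correlation alone. Inhibitory neuron markers, with an estimated correlation of -0.054, went from a camera adjusted p of 0.0172 to 0.382 against scrambled siRNA.

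On data simulated for Baf53b siRNA against scrambled siRNA with 14657 genes and 200 changed genes (100 per fold size) in each of 20 datasets, 73.0% of genes changed 2-fold and 99.2% of genes changed 4-fold were recovered. Of all calls 7.84% were unchanged genes, above the nominal level. The recovered shares hold for that number of changed genes and for errors drawn from the spread estimated by limma. They do not give the share of 2-fold changes that the data would show. In the data 93 genes were higher and 26 lower by more than 1 (log2) against scrambled siRNA. Of these 18 were called, the lowest at 1.20. A list shifted by 0.5 (log2) was called in all 20 datasets, and 4 other lists were called in total. Errors were drawn independently for each gene, so simulated lists held no inter-gene correlation. Correlations estimated from the data ranged from -0.12 (hippocampal markers) to 0.88 (mitochondrially encoded genes). The simulation therefore cannot say how often camera calls an unchanged list whose members correlate.

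Genes were named by a rule fixed before the data were examined. Actl6b and Actl6a were named first. For Baf53b siRNA against scrambled siRNA these were, per direction, the 10 genes with the largest log2 difference among those with an adjusted p under 0.05 and no overlap between the libraries of the groups, filled up where fewer passed by the smallest unadjusted p among genes differing by at least 0.3. The other comparisons followed the same rule with 5 genes per direction. Predicted genes, clones and pseudogenes were counted but took no place; pseudogenes were read from the annotated gene type as well as from the symbol, which keeps H2-Q5 out, and a clone name with a digit after its ending was not recognised as a clone. For each list at most 4 members past the threshold were eligible, or the 2 with the smallest unadjusted p where none passed. The text names a part of the list members so chosen, and single values of some members are not reported here.

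Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, median-of-ratios scaling, rescaling to a fixed sum (TPM), quantile normalization, eBayes without trend or with robust, fits of the compared groups alone, the replicate number as a block (alone and with median-of-ratios scaling), small RNA genes kept, failed estimates kept, the highest row per gene, each library left out, a threshold of 0.1, and camera on ranks. A rescaling without mitochondrial genes and lists without 6 antigen presentation members (H2-D1, H2-Aa, H2-Ab1, H2-Eb1, Cd74 and Psmb8) were chosen after seeing the data.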

Results

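RNA was sequenced from the lateral amygdala, a brain region needed for fear memory, of male mice of a 129xC57BL/6 hybrid strain. The study asked about BAF53b, a subunit of the BAF nucleosome remodelling complex found in neurons and encoded by the gene Actl6b. There were 3 groups of 2 libraries each, named control, scrambled siRNA (a small interfering RNA of shuffled sequence) and Baf53b siRNA (a small interfering RNA against Actl6b, injected 1 day after training). The labels mention tissue from 4 mice but do not say whether each library holds a pool of animals, and they do not say what the control mice received. The p-values therefore measure the spread between these libraries. Gene levels were deposited as FPKM (fragments scaled by transcript length and by the mapped fragments of the library) without read counts. The width of the deposited confidence intervals implied between 6.43 M fragments (scrambled siRNA replicate 1) and 10.7 M fragments (scrambled siRNA replicate 2) behind the genes of a library, an estimate that covers counting error only. Differences below are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM, and SE is the standard error of the limma fit.

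The first question was whether the targeted transcript was lower in the libraries labelled Baf53b siRNA. Actl6b (ENSMUSG00000029712.14, mm10 chromosome 5, 137553517 to 137569582, plus strand, a protein-coding gene) stood at 42.9 and 44.1 FPKM in the control libraries. It stood at 43.8 and 43.9 FPKM in the scrambled siRNA libraries and at 42.8 and 39.6 FPKM in the libraries labelled Baf53b siRNA. The group means were 43.5 ± 0.888 FPKM (SD, n = 2), 43.8 ± 0.0883 FPKM (SD, n = 2) and 41.2 ± 2.24 FPKM (SD, n = 2). The log2 difference between Baf53b siRNA and scrambled siRNA was -0.09 (SE 0.12, 95% interval -0.38 to 0.21, limma adjusted p = 1), so a fall was not detectable, and the interval excludes a reduction larger than 23.3%. Against control the difference was -0.08 (SE 0.12, adjusted p = 1 in limma). Both libraries labelled Baf53b siRNA lay below the other 4 libraries, the nearest values being 42.79 FPKM (Baf53b siRNA replicate 1) and 42.86 FPKM (control replicate 1). A two-sided exact permutation test gave p = 0.0667 for this order, the smallest p that 2 libraries against 4 can give. The difference of -0.09 against scrambled siRNA lay between the quartiles (-0.16 and -0.04) of 54 neuron markers, which were grouped after the results were seen. An exact permutation test of 2 libraries against 2 cannot go below 0.333. Actl6a (ENSMUSG00000027671.14, chromosome 3, 32706298 to 32726973, plus strand), the paralogous subunit of dividing cells, was at 5.59 and 3.65 FPKM in control, 6.36 and 4.12 FPKM in scrambled siRNA and 6.34 and 5.98 FPKM in Baf53b siRNA libraries (log2 difference 0.22 between Baf53b siRNA and scrambled siRNA, SE 0.24, adjusted p = 1 in limma). Because Actl6b did not differ detectably, every direction below refers to the libraries as labelled.

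**Figure D1:**
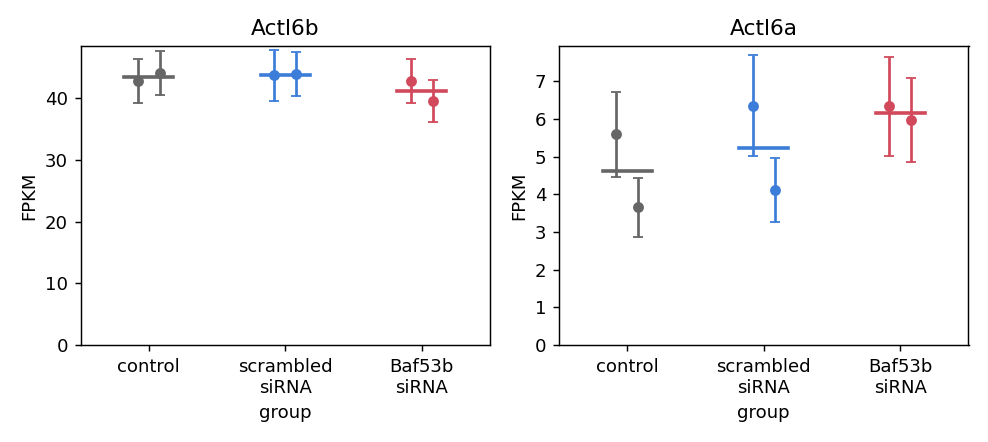
FPKM of Actl6b and Actl6a in each of the 6 libraries by group. Points are libraries, vertical bars the deposited 95% confidence intervals and horizontal lines group means; the 6 Actl6b values lie between 39.6 and 44.1 FPKM.

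The second comparison set the libraries labelled Baf53b siRNA against scrambled siRNA. There were 18 genes higher in the libraries labelled Baf53b siRNA, among them Cd74, H2-Aa, H2-Ab1, C3 and Gfap, and 0 called lower (limma). Cd74 (ENSMUSG00000024610.14, chromosome 18, 60803848 to 60812646, plus strand), the invariant chain that accompanies class II histocompatibility molecules, rose from 8.56 ± 1.67 FPKM (SD, n = 2) to 157 ± 76.6 FPKM (SD, n = 2), a log2 difference of 3.96 (SE 0.36, limma adjusted p = 0.0302). The class II chains H2-Aa and H2-Ab1 rose by 3.47 and 3.24, and the class I heavy chain H2-D1 rose by 2.06. Gfap (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament of astrocytes, rose from 46.2 ± 1.54 FPKM (SD, n = 2) to 174 ± 5.45 FPKM (SD, n = 2), a log2 difference of 1.89 (SE 0.13, limma adjusted p = 0.0110). C3 (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136, minus strand), the central complement protein, rose by 2.81 from 0.671 FPKM to 10.6 FPKM.

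Of 14657 genes tested, 18 were higher and 0 were lower at an adjusted p under 0.05 in limma, and 444 had an unadjusted p under 0.05, of which 391 were higher and 53 lower. The interferon-induced GTPases Tgtp2 and Iigp1 rose by 2.01 and 1.76. Cst7, a cysteine protease inhibitor, rose by 1.85, and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose by 1.75. The other 8 called genes were C4b (1.66), Oasl2 (1.61), Psmb9 (1.58), Gbp6 (1.57), Irgm1 (1.41) and Mpeg1 (1.20), and H2-Q5 (2.35) and C920009B18Rik (4.41), both annotated as pseudogenes. The naming rule did not reach these 8, which were named after their values were seen. Among the genes followed over 23 alternative settings, the call was lost in 2 for C3 and Gfap and in 6 for Cd74. It was lost in 7 for H2-D1 and Tgtp2, in 8 for H2-Ab1, Cst7, Cybb and Iigp1, and in 10 for H2-Aa and C4b. Settings in which a gene failed the filter on low values, and so was not tested, are not among these losses. C3, Tgtp2, Cst7, Cybb and Iigp1 were not tested at a mean FPKM of at least 5. Cst7, Cybb and Iigp1 were also not tested when either Baf53b siRNA library was left out, nor was Tgtp2 without Baf53b siRNA replicate 1. In all 18 genes both libraries labelled Baf53b siRNA lay above both scrambled siRNA libraries, an order that 1 of the 6 splits of 4 libraries into pairs gives by chance. Reads of the H2 genes, of C4b and C4a, and of the Gbp and Tgtp genes can be shared between near-identical copies, so the split among copies is uncertain.

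No gene was called lower. The 10 genes with the smallest unadjusted p among those lower by at least 0.3 did not pass (limma adjusted p of 0.270 or more). Fgf9 and Fgf1, fibroblast growth factors, differed by -0.51 and -0.78, and the homeobox gene Emx2 by -0.51. Cort, which encodes the neuropeptide cortistatin, differed by -0.51. The others were Mycbp (-0.90), Ccdc91 (-1.14), Adamts17 (-0.49), Cdpf1 (-0.51), Pcca (-0.52) and the short Y RNA gene Rny3. Rny3 was listed at 0 in both libraries labelled Baf53b siRNA and in control replicate 1, and stood at 31.8 FPKM in control replicate 2 and at 222 and 85.9 FPKM in scrambled siRNA. It passed as lower without control replicate 1 (limma adjusted p = 0.0124), without control replicate 2 (0.00839) and in a fit of the compared groups alone (0.00654), and its adjusted p was 0.255 or more in every other setting.

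**Figure D2:**
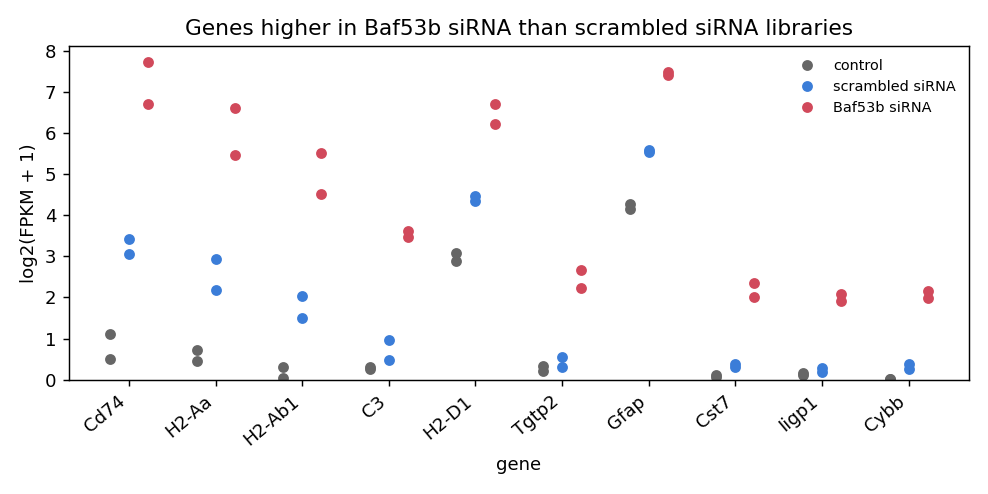
Level of the 10 named genes higher in Baf53b siRNA than scrambled siRNA libraries, as log2(FPKM + 1), with 1 point per library. The red points (Baf53b siRNA) lie above the blue (scrambled siRNA) and gray (control) points in every gene, as for Gfap with group means of 174, 46.2 and 17.6 FPKM.

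The 34 gene lists fixed before the data were examined placed these genes. Of 17 tested reactive astrocyte and injury genes, 4 rose (C3, H2-D1, Gfap and C4b), 13 did not pass, and 11 rose when adjusted over the list alone. This list was higher than other genes in limma's camera test (median log2 difference 0.97, adjusted p = 1.24e-38). It was the 1 list that held in camera with an estimated correlation (adjusted p = 0.0417 with an estimated correlation). That setting also has fewer degrees of freedom, so a list that fails there need not fail through correlated members. Of 20 infiltrating leukocyte markers 8 were tested, among them Cd74, H2-Aa, H2-Ab1 and H2-Eb1 of antigen presentation. Of these 8, 3 rose (Cd74, H2-Aa and H2-Ab1), and 7 rose when adjusted over the list alone (median 2.73, camera adjusted p = 3.98e-30, adjusted p = 0.0719 with an estimated correlation). Most markers of this list were not tested, so its median does not stand for the whole list. Of 16 interferon-stimulated genes, Oasl2 rose (a call lost in 13 settings, among them each of the 6 that left a library out), 15 did not pass, and 13 rose when adjusted over the list alone (median 0.83, camera adjusted p = 1.47e-33, adjusted p = 0.0773 with an estimated correlation). None of 20 microglia markers passed over all genes, while 10 rose when adjusted over the list alone (median 0.50, camera adjusted p = 7.72e-23, adjusted p = 0.166 with an estimated correlation); Ctss, a lysosomal protease, was at 127 and 244 FPKM and the complement gene C1qc at 58.8 and 103 FPKM in scrambled siRNA and Baf53b siRNA. Among 14 cytokines and chemokines none passed and 3 rose when adjusted over the list alone (median 0.32, camera adjusted p = 7.58e-09, adjusted p = 0.382 with an estimated correlation), with the chemokine Ccl5 at 0.508 and 24.6 FPKM (limma adjusted p = 0.0532, and 0.0279 and 0.00700 without Baf53b siRNA replicates 1 and 2) and Ccl6 at 1.19 and 3.65 FPKM.

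Among 17 endothelial markers none passed (median 0.16, camera adjusted p = 0.00942, adjusted p = 0.819 with an estimated correlation); Pecam1 was at 3.43 and 4.37 FPKM and Ly6a at 18.3 and 21.6 FPKM. There were 5 lists lower than other genes in camera by small medians, none of whose members passed. They were presynaptic vesicle release (24 of 24 members lower by sign, median -0.13, camera adjusted p = 6.24e-05, adjusted p = 0.635 with an estimated correlation), voltage-gated ion channels (-0.06, camera adjusted p = 0.0130, adjusted p = 0.635 with an estimated correlation), inhibitory neuron markers (-0.07, camera adjusted p = 0.0172, adjusted p = 0.382 with an estimated correlation), oxidative phosphorylation subunits (-0.07, camera adjusted p = 0.00236, adjusted p = 0.819 with an estimated correlation) and haemoglobin and erythroid genes (-0.17, camera adjusted p = 0.0217, adjusted p = 0.530 with an estimated correlation). Examples were the complexin Cplx1 at 93.0 and 76.8 FPKM, the sodium channel subunit Scn2b at 36.9 and 31.7 FPKM and the interneuron marker Pvalb at 7.93 and 6.15 FPKM. Inhibitory neuron markers passed fry (adjusted p = 0.00848, and 0.000844 against control) but not its mixed test (0.478 and 0.838). The presynaptic, ion channel, oxidative phosphorylation and haemoglobin lists did not pass fry against scrambled siRNA (adjusted p = 0.945). The camera calls of the endothelial list and of these 5 lists were each lost without at least 1 library. Without scrambled siRNA replicate 1 the endothelial (adjusted p = 0.162), haemoglobin (0.217) and oxidative phosphorylation (0.124) calls were lost, and without scrambled siRNA replicate 2 the ion channel (0.352) and inhibitory neuron (0.495) calls. Without Baf53b siRNA replicate 1 the inhibitory neuron (0.240) and haemoglobin (0.917) calls were lost, and without Baf53b siRNA replicate 2 the presynaptic (0.158), ion channel (0.150), oxidative phosphorylation (0.870) and endothelial (0.870) calls. The other 5 lists called higher passed camera with any library left out.

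The lists closest to the target of the siRNA showed no called gene. The 28 tested BAF subunits had a median log2 difference of -0.02, with Brd7 at 28.0 and 25.4 FPKM and Ss18 at 6.53 and 7.43 FPKM in scrambled siRNA and Baf53b siRNA. Chromatin and DNA methylation regulators had a median of 4e-05, which turned negative under 3 other scalings, with Creb1 at 9.49 and 10.9 FPKM, and dendrite growth and actin regulators a median of -0.05, with Kalrn at 93.8 and 80.4 FPKM. Activity-induced immediate early genes had a median of 0.05 (-0.02 under quantile normalization), with Fos at 3.21 and 4.81 FPKM. None of their members passed, also when adjusted over the list alone, and none of these lists passed in camera. The remaining lists did not pass in camera either. Their medians were -0.03 (glutamate receptors and postsynaptic density), -0.07 (excitatory neuron markers), -0.08 (neuropeptides), -0.03 (striatal neurons), -0.12 (thalamic and habenular markers), 0.07 (hypothalamic markers), -0.06 (hippocampal markers), 0.03 (astrocyte markers, -0.0063 under quantile normalization), 0.05 (RNA interference and nucleic acid sensing) and -0.07 (oligodendrocyte and myelin genes). They were 0.08 for oligodendrocyte precursors, 0.02 for pericytes and smooth muscle (negative under 2 other scalings), -0.08 for choroid plexus and ependyma, 0.07 for fibroblasts, 0.02 for extracellular matrix, 0.01 for cytosolic ribosomal proteins (negative under 2 other scalings), -0.05 for mitochondrially encoded genes (0 under quantile normalization), -0.04 for heat shock genes and 0.11 for glucocorticoid-induced genes. The median, mean and camera direction differed in sign for the thalamic, mitochondrially encoded and fibroblast lists. With a library left out some of these lists passed camera. Without scrambled siRNA replicate 1 they were the excitatory neuron, astrocyte, nucleic acid sensing, oligodendrocyte, ribosomal and mitochondrially encoded lists (adjusted p of 0.0389 or less), and without scrambled siRNA replicate 2 the mitochondrially encoded list (0.0248). Without Baf53b siRNA replicate 1 they were the dendrite, nucleic acid sensing, choroid plexus and ribosomal lists (0.0489 or less), and without Baf53b siRNA replicate 2 the immediate early, oligodendrocyte, choroid plexus and ribosomal lists (0.0123 or less). Without control replicate 1 the neuropeptide list passed (0.0409). 1 astrocyte marker, the water channel Aqp4, passed when adjusted over the list alone, at 21.3 and 33.4 FPKM.

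In the shared counts below, a gene that failed the filter on low values counts as not called. This holds for Cst7, Cybb, Iigp1 and Gbp6 when either Baf53b siRNA library was left out. The count of 18 moved with single libraries and with the treatment of low values. It was 4 without control replicate 1 (3 higher, 1 lower) and 7 without control replicate 2 (6 higher, 1 lower), although control libraries enter this comparison through the estimate of the spread and the filter on low values and not through the log2 differences. It was 7 without scrambled siRNA replicate 1 (2 higher, 5 lower), 9 without scrambled siRNA replicate 2 (4 higher, 5 lower), 1 with a pseudocount of 0.1, 0 without a filter on low values, 5 with small RNA genes kept (4 higher, 1 lower) and 8 at a mean FPKM of at least 5. With a library left out, 2 to 8 of the 18 genes were called again; without Baf53b siRNA replicate 1 there were 13 genes (12 higher, 1 lower), 5 of them shared, and without Baf53b siRNA replicate 2 there were 23, 8 of them shared.

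The third comparison set the libraries labelled Baf53b siRNA against control. Here 181 genes were higher and 0 lower (limma, adjusted p under 0.05; 735 genes at an unadjusted p under 0.05, 695 higher and 40 lower). The largest difference was that of Cd74, which rose by 6.40 (SE 0.36, limma adjusted p = 0.00138) from 0.798 ± 0.540 FPKM (SD, n = 2) in control, and H2-Aa, H2-Eb1 and H2-Ab1 rose by 5.44, 4.94 and 4.83. Saa3, an acute phase protein gene, rose by 5.79 (SE 0.58), with 99.3 and 32.4 FPKM in the libraries labelled Baf53b siRNA against 0.0340 and 0.0566 FPKM in control. Of 20 microglia markers 11 rose, among them C1qa (34.1 to 146 FPKM) and Ctss (60.0 to 244 FPKM), and 17 rose when adjusted over the list alone. Of 17 reactive astrocyte and injury genes 12 rose, both over all genes and when adjusted over the list alone; Gfap rose by 3.23, and Lcn2, a secreted iron-carrier binding protein, was listed at 0 in both control libraries and stood at 9.88 and 10.2 FPKM in the libraries labelled Baf53b siRNA. Of 16 interferon-stimulated genes 11 rose, including Oasl2 (2.21) and Bst2 (2.31), and 15 when adjusted over the list alone. Of the 8 tested leukocyte markers 7 rose, and 8 when adjusted over the list alone. Of 14 cytokine and chemokine genes 5 rose, including Ccl5 (4.28) and Ccl12 (2.58), and 10 when adjusted over the list alone. Of the 181 genes, 180 were also higher in scrambled siRNA than control by sign, with both scrambled siRNA libraries above both control libraries in 170. Their median log2 difference was 0.58 between scrambled siRNA and control and 0.82 between Baf53b siRNA and scrambled siRNA. For Lcn2 the values were 2.78 and 0.68, for Ccl12 2.05 and 0.53, and for Ccl5 0.44 and 3.84. Both comparisons with control share the control libraries, which sets them alike when nothing changes.

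Elsewhere 1 astrocyte marker (Aqp4, 0.80) and 1 gene of the thalamic list (Prkcd, a protein kinase C, 1.17) rose, and no other list had a called member. Each of these calls was lost in 15 settings, among them each of the 6 that left a library out. The 5 genes lower with the smallest unadjusted p did not pass: Kbtbd4 (-0.74), Emx2 (-0.58), Nckap5 (-0.53), and the cilium-associated genes Ccdc153 (-1.49) and Tmem107 (-0.62). In camera 9 lists were higher and 9 lower than other genes, of which 1, reactive astrocyte and injury genes, held with an estimated correlation (adjusted p = 0.0497 with an estimated correlation). The adjusted p with an estimated correlation was 0.0723 for microglia markers (median 1.09), 0.0680 for leukocyte markers (4.33) and for interferon-stimulated genes (1.50), and 0.186 for cytokines and chemokines (0.94). It was 0.540 for nucleic acid sensing (0.14, 4 genes higher when adjusted over the list alone), 0.540 for oligodendrocyte and myelin genes (0.18), 0.487 for endothelial markers (0.25, 1 gene higher when adjusted over the list alone) and 0.654 for cytosolic ribosomal proteins (0.20). For the lower lists it was 0.184 for inhibitory neuron markers (median -0.10), 0.186 for neuropeptides (-0.13) and 0.396 for excitatory neuron markers (-0.07), choroid plexus and ependymal markers (-0.20) and haemoglobin and erythroid genes (-0.19). It was 0.592 for presynaptic vesicle release (-0.05), 0.540 for voltage-gated ion channels (-0.01), 0.702 for glutamate receptors and postsynaptic density (-0.03) and 0.592 for mitochondrially encoded genes (-0.24). The median, mean and camera direction differed in sign for the BAF, dendrite, thalamic, pericyte and oxidative phosphorylation lists, none of which passed. Of the 18 list calls 6 passed camera with any library left out, the 5 immune and glial lists and inhibitory neuron markers. Without control replicate 1 the glutamate receptor, ion channel, oligodendrocyte and ribosomal calls were lost (adjusted p of 0.542 or more), and without control replicate 2 the excitatory neuron, neuropeptide, choroid plexus, haemoglobin and mitochondrially encoded calls (0.154 or more). Without Baf53b siRNA replicate 1 the excitatory neuron, choroid plexus, haemoglobin, ribosomal and mitochondrially encoded calls were lost (0.0797 or more), and without Baf53b siRNA replicate 2 the glutamate receptor, presynaptic, ion channel, excitatory neuron, nucleic acid sensing, oligodendrocyte and endothelial calls (0.102 or more). The count of 181 was 65 without control replicate 1 (58 higher, 7 lower), 62 without control replicate 2 (58 higher, 4 lower), 34 without Baf53b siRNA replicate 1, 80 without Baf53b siRNA replicate 2, 71 at a mean FPKM of at least 5 and 42 without a filter on low values, the last 4 all higher. With small RNA genes kept 125 were higher and 5 lower, and other settings gave at most 2 lower.

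The fourth comparison set scrambled siRNA against control, and no gene passed (0 genes in limma, smallest adjusted p = 0.216, 325 genes at an unadjusted p under 0.05, 298 higher and 27 lower). Gfap had the smallest unadjusted p. It stood at 17.6 ± 1.03 FPKM (SD, n = 2) in control and 46.2 ± 1.54 FPKM (SD, n = 2) in scrambled siRNA (log2 difference 1.35, SE 0.13, limma adjusted p = 0.216). Cd52, a leukocyte surface protein gene, differed by 2.06, H2-D1 by 1.42, C4b by 1.20 and Ctss by 1.07, each with a limma adjusted p of 0.328. The lower genes with the smallest unadjusted p were Mllt10 (-0.48), Efcab10 (-0.44), Ripply2 (-0.42), Rsph1 (-0.38) and Mtrf1l (-0.43), all with a limma adjusted p of 1. In camera 9 lists were higher and 3 lower, and none held with an estimated correlation. Microglia markers (20 of 20 higher by sign, median 0.60), reactive astrocyte and injury genes (median 0.29) and leukocyte markers (median 1.60) each had an adjusted p = 0.110 with an estimated correlation. The adjusted p with an estimated correlation was 0.150 for interferon-stimulated genes (0.53), 0.380 for oligodendrocyte and myelin genes (0.25) and 0.418 for cytokines and chemokines (0.35). It was 0.738 for nucleic acid sensing (0.11), endothelial markers (0.14), cytosolic ribosomal proteins (0.18) and mitochondrially encoded genes (-0.22), and 0.418 for hypothalamic (-0.16) and choroid plexus and ependymal markers (-0.36). When adjusted over the list alone, 13 microglia markers, 7 leukocyte markers, 6 interferon-stimulated genes, 5 reactive astrocyte genes and 2 cytokine genes were higher. The median or mean and the camera direction differed in sign for 10 lists that did not pass (BAF, chromatin, immediate early, dendrite, ion channel, neuropeptide, striatal, pericyte, haemoglobin and heat shock lists). The camera calls of the microglia, reactive astrocyte, leukocyte, interferon and cytokine lists stood with any library left out, and the other 7 were each lost without at least 1 control or scrambled siRNA library. Without control replicate 1 these were the hypothalamic, oligodendrocyte and ribosomal calls (adjusted p of 0.372 or more), and without control replicate 2 the nucleic acid sensing, endothelial, choroid plexus and mitochondrially encoded calls (0.239 or more). Without scrambled siRNA replicate 1 they were the nucleic acid sensing, ribosomal and mitochondrially encoded calls (0.266 or more), and without scrambled siRNA replicate 2 the hypothalamic, endothelial and choroid plexus calls (0.0822 or more). The count of 0 became 7 without control replicate 1 (1 higher, 6 lower), 4 without control replicate 2 (1 higher, 3 lower), 6 without either scrambled siRNA library (5 higher, 1 lower) and 1, higher, without either Baf53b siRNA library.

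**Figure D3:**
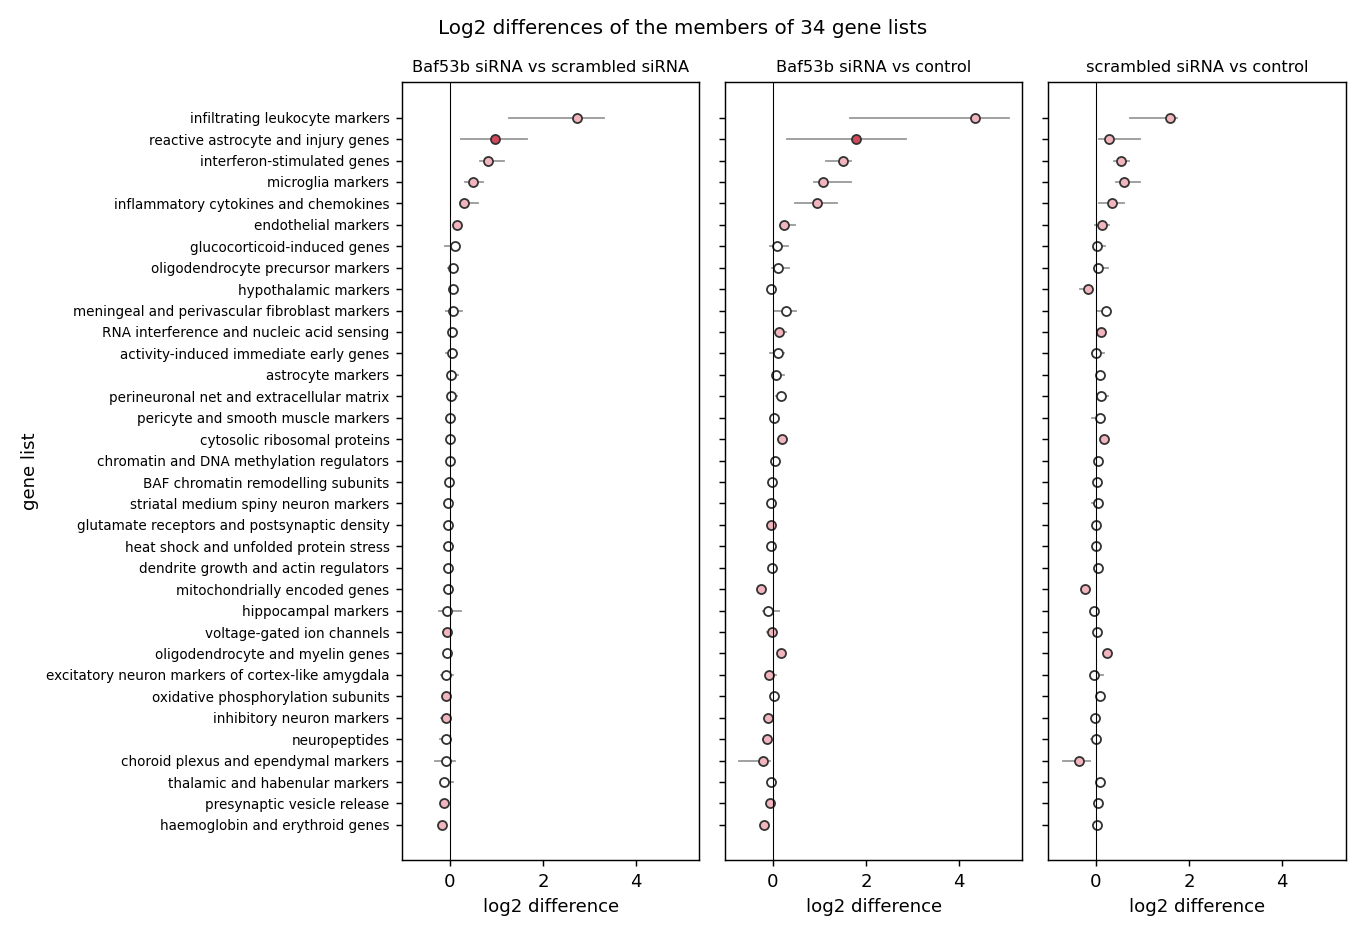
Median log2 difference (points) and quartiles (gray lines) over the tested members of 34 gene lists in the 3 comparisons. Pale red points passed camera with a preset correlation of 0.01 and dark red points also with an estimated correlation, which in the first panel is the reactive astrocyte and injury list with a median of 0.97.

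The calls of both comparisons of the libraries labelled Baf53b siRNA overlapped: all 18 genes higher against scrambled siRNA were among the 181 higher against control. These comparisons share the Baf53b siRNA libraries. Unchanged groups simulated 100 times, with errors independent between genes and libraries, gave a mean overlap of 0.03 and a maximum of 1. Since no gene changes in this simulation, few are called. It therefore cannot say how far lists of 18 and 181 genes would overlap through the shared libraries. Independent lists of these sizes would share 0.222 genes. The log2 differences of the pair of comparisons had a covariance across genes of 0.0614, against 0.0242 in simulation, and a correlation across genes of 0.748, against 0.502. The simulation drew every library independently, whereas deviations of same-numbered libraries correlated by 0.18 to 0.39 in the data. With 2 libraries a group could not be split, so part of the excess may come from the shared libraries. Of the 18 genes, 17 were also higher in scrambled siRNA than in control by sign, with a median log2 difference of 0.43 (11 genes and 0.19 under quantile normalization, 17 genes and 0.41 to 0.60 under the other scalings), and in 15 of them both scrambled siRNA libraries lay above both control libraries. Over all 14657 genes 9317 were higher in scrambled siRNA than control by sign. The comparisons of Baf53b siRNA with scrambled siRNA and of scrambled siRNA with control share the scrambled siRNA libraries, which sets their differences against each other when nothing changes. Over all genes 40.7% had the same sign in both, against 33.3% in the simulation, with a correlation across genes of -0.09 against -0.50 and a covariance of -0.00495 against -0.0242.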

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

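The tests in this part were all chosen after the values were seen. Synthetic spike-in RNA, which enters none of the comparisons, took a larger share of the FPKM sum in the 4 siRNA libraries than in the control libraries (0.0191% and 0.0195%): 0.0340% and 0.102% in scrambled siRNA replicates 1 and 2, and 0.755% and 0.128% in Baf53b siRNA replicates 1 and 2. The highest spike-in FPKM sum was 41.2 times the lowest, which argues against an equal amount relative to the other RNA of each library. FPKM is relative to the fragments of the library, and RNA input did not enter the test. An equal amount added to unequal RNA therefore cannot be told apart from an uneven addition. Carry-over from other libraries handled together stays open and cannot be told apart from an uneven addition, since both give 1 profile across spike-in transcripts (correlation across transcripts 0.96 between the Baf53b siRNA libraries). No biological explanation was tested. Without Baf53b siRNA replicate 1, the library with the largest share, 13 genes differed from scrambled siRNA (5 of them among the 18) and 34 from control (29 of them among the 181).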

How the results depend on the processing

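All alternatives but the rescaling without mitochondrial genes and the lists without antigen presentation members were fixed before the data were examined, and unless stated the cause of a change was not tested. Actl6b (Baf53b siRNA against scrambled siRNA) stayed between -0.14 and -0.03 and past the threshold in none of 23 settings (-0.14 to -0.03 with a library left out). The 18 genes of that comparison became 1 with a pseudocount of 0.1, 0 of 29381 genes with no filter, 8 at a mean FPKM of at least 5 (fewer genes tested), 29 without trend, 30 with robust, 28 with the replicate block and median-of-ratios scaling, 5 (4 higher) with small RNA genes kept, and 37 at 0.1 (a looser threshold); genes called both against scrambled siRNA and against control numbered the same in each of these. Other settings with all libraries gave 13 to 27 genes. With a library left out, which leaves a lone library assumed to vary like the others, counts ranged from 4 to 23 (2 to 8 of the 18 shared) and those in both comparisons from 2 to 23. The 181 genes against control became 42 with no filter (20 shared) and 71 at a mean FPKM of at least 5 (71 shared), 130 to 238 in other settings with all libraries, and 34 to 139 with a library left out. The 0 genes of scrambled siRNA against control became 1 in a fit of those groups alone and 1 to 7 with a library left out.

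The lists called (11, 18 and 12 in the order of the comparisons) became 1, 1 and 0 with an estimated correlation and 4, 5 and 0 with fry, whose mixed test called 5, 7 and 1; with a library left out they ranged over 10 to 14, 11 to 19 and 9 to 13. Without antigen presentation members they were 10, 17 and 11, since the leukocyte list then had too few members. The median of mitochondrially encoded genes became 0 in all 3 comparisons under quantile normalization, because that setting gives the most abundant genes equal values. Other list medians that changed sign, for Baf53b siRNA against scrambled siRNA and past the threshold in none of the settings where they did, were those of immediate early genes (-0.016) and pericytes (-0.00075) under quantile normalization, and of hypothalamic markers without a filter (-0.0016). The astrocyte median also turned under quantile normalization (-0.0063), where the list passed camera as higher than other genes. The chromatin list turned at a mean FPKM of at least 5 (-0.0066), under median-of-ratios scaling (-0.0015, also with the replicate block), TPM (-0.016) and scaling without mitochondrial genes (-0.019). Ribosomal proteins turned under TPM (-0.0071) and without mitochondrial genes in the scaling (-0.0098), as did pericytes under the latter (-0.00016). Lists and genes named by the rule that changed direction with a library left out are given with their lowest and highest log2 difference over those fits; for lists past the threshold the direction is that of camera. For Baf53b siRNA against scrambled siRNA these lists were BAF chromatin remodelling subunits (-0.10 to 0.084), dendrite growth and actin regulators (-0.12 to 0.038), glutamate receptors and postsynaptic density (-0.091 to 0.067), thalamic and habenular markers (-0.20 to 0.071), choroid plexus and ependymal markers (-0.49 to 0.31), meningeal and perivascular fibroblast markers (-0.21 to 0.068), heat shock and unfolded protein stress (-0.11 to 0.030), chromatin and DNA methylation regulators (-0.11 to 0.14), activity-induced immediate early genes (-0.15 to 0.21), hypothalamic markers (-0.074 to 0.23), astrocyte markers (-0.029 to 0.14), RNA interference and nucleic acid sensing (-0.023 to 0.14), oligodendrocyte precursor markers (-0.11 to 0.16), pericyte and smooth muscle markers (-0.16 to 0.24), perineuronal net and extracellular matrix (-0.060 to 0.16), cytosolic ribosomal proteins (-0.15 to 0.19), mitochondrially encoded genes (-0.29 to 0.21), glucocorticoid-induced genes (-0.036 to 0.16), striatal medium spiny neuron markers (-0.12 to 0.032) and endothelial markers (0.039 to 0.23). For Baf53b siRNA against control these lists were oligodendrocyte and myelin genes (0.072 to 0.30) and mitochondrially encoded genes (-0.60 to 0.13). For scrambled siRNA against control these lists were cytosolic ribosomal proteins (-0.0075 to 0.33) and mitochondrially encoded genes (-0.56 to 0.12). Of these, mitochondrially encoded genes without scrambled siRNA replicate 2 (0.21, adjusted p = 0.0248), choroid plexus markers without Baf53b siRNA replicate 1 (0.29, adjusted p = 0.0489) and ribosomal proteins without Baf53b siRNA replicate 1 (-0.13, adjusted p = 0.0200) passed camera against scrambled siRNA. For Baf53b siRNA against scrambled siRNA these genes were Ngef (-0.32 to 0.019), Rgs5 (-0.13 to 0.35), Kalrn (-0.43 to 0.019), mt-Atp8 (-0.59 to 1.66), mt-Nd3 (-0.25 to 0.57), Rarres2 (-0.014 to 0.43), Actl6a (-0.040 to 0.48), Baiap3 (-0.11 to 0.37), Ccdc153 (-1.20 to 0.25) and Ss18 (-0.0039 to 0.31). For Baf53b siRNA against control these genes were Ociad2 (-0.52 to 0.086), Cox7b (-0.95 to 0.15), mt-Nd4 (-0.62 to 0.058), mt-Nd5 (-0.53 to 0.047) and Rgs5 (-0.047 to 0.43). For scrambled siRNA against control these genes were Wfs1 (-0.32 to 0.085), Spink8 (-0.17 to 0.40), Kmt2b (-0.10 to 0.57), Cacnb4 (-0.0092 to 1.30), Actl6a (-0.11 to 0.41), Hsph1 (-0.35 to 0.048), Drd1 (-0.39 to 7.8e-05), mt-Atp8 (-1.78 to 0.47), Homer3 (-0.29 to 0.011), Acta2 (-0.73 to 0.032) and Hbb-bs (-0.36 to 0.052). None of these genes passed in either fit, and no named gene past the threshold changed sign. Settings in which a gene failed the filter on low values add nothing to the following counts of gene calls lost or gained. In settings with all libraries, named genes lost their call 43 times (Baf53b siRNA against scrambled siRNA) and 40 times (against control) and gained one 6 and 14 times; with a library left out they lost it 46 and 40 times and gained it 4 and 0 times. Lists lost their call with the camera direction kept 21, 41 and 28 times with all libraries and 10, 19 and 10 times with a library left out. Called lists that turned direction and lost their call, such as mitochondrially encoded genes under quantile normalization, are not in these counts. Gains of lists were followed for Baf53b siRNA against scrambled siRNA alone. With the camera direction kept there were 8 with all libraries and 13 with a library left out. The mitochondrially encoded, choroid plexus and ribosomal lists given above as passing after a turn of direction are not among the 13. The 8 were neuropeptides on ranks (adjusted p = 0.0462), under TPM (0.0462), in a fit of those groups alone (0.0456) and at the looser threshold of 0.1 (0.0613), thalamic (0.0237) and astrocyte (0.0381) markers at a mean FPKM of at least 5, and astrocyte markers (0.0352) and ribosomal proteins (0.00514) under quantile normalization.

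The replicate numbers are shared by the groups but the labels do not say that they mark a batch. Deviations of same-numbered libraries correlated across genes by 0.39, 0.18 and 0.36. Across genes, same-numbered control and scrambled siRNA libraries correlated by 0.985 and 0.986, against 0.975 within control and 0.980 within scrambled siRNA. Same-numbered scrambled and Baf53b siRNA libraries correlated by 0.982 and 0.984, and control and Baf53b siRNA by 0.977 and 0.972, against 0.981 within Baf53b siRNA. The axis of largest variance (39.5%) put replicate 1 below replicate 2 in each group. Leaving a library out therefore also unbalances the replicate numbers. The replicate block gave 13, 188 and 0 genes in place of 18, 181 and 0, with 10 of the 18 and 160 of the 181 shared. With 2 libraries a group, other splits of the libraries were not counted, and depth was known only from the intervals.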

Other observations

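The gene families in this paragraph were chosen after the called genes were seen, so their counts of called genes are given without a test. Among the 181 genes higher in the libraries labelled Baf53b siRNA than in control were all 5 tested genes with Fc receptor symbols (Fcgr1, Fcgr2b, Fcgr3, Fcgr4 and Fcer1g). Fcgr3 was at 8.11 and 9.23 FPKM in control and 27.7 and 24.5 FPKM in Baf53b siRNA. The 181 genes also held 10 of 11 immunity-related and guanylate-binding GTPases. Igtp was at 0.780 and 0.782 FPKM in control and 8.08 and 4.90 FPKM in Baf53b siRNA. Of 18 H2 genes 12 were called, of 6 complement components 5, and of 5 NADPH oxidase subunits 4, among them Ncf1. Of 10 lysosomal cathepsins 4 were called, with Ctsc at 2.85 and 3.20 FPKM in control and 12.6 and 11.4 FPKM in Baf53b siRNA. Of 6 interferon regulatory factors 2 were called and of 5 Toll-like receptors 1. The median of each family stayed above 0 under 4 other scalings, and under quantile normalization limma called 3 Fc receptors, 8 GTPases, 11 H2 genes, 5 complement components, 4 NADPH oxidase subunits, 5 cathepsins, 1 interferon regulatory factor and 0 Toll-like receptors.

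The median log2 differences of these families, given without a test, were 0.82 between scrambled siRNA and control and 0.66 between Baf53b siRNA and scrambled siRNA for Fc receptors, 0.24 and 1.41 for the GTPases and 0.63 and 1.55 for H2 genes. They were 1.07 and 0.96 for complement components, 0.67 and 0.78 for NADPH oxidase subunits, 0.36 and 0.46 for cathepsins, 0.27 and 0.43 for interferon regulatory factors and 0.49 and 0.35 for Toll-like receptors.

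The tests in the rest of this part were chosen after the results were seen. The first pattern is the 18 genes, among them Cd74 and Gfap, higher in the libraries labelled Baf53b siRNA than in scrambled siRNA. The median log2 difference of the 18 called genes was at least 1.86 under 4 other scalings, while the median of all genes lay between -0.016 and 0.0013 there, which argues against unequal scaling. A larger share of microglia cannot be told apart from a change within cells: the 20 microglia markers had a median of 0.50 (quartiles 0.34 and 0.71, highest 0.951, none called) against scrambled siRNA, below the lowest of the 18 genes at 1.20, and of 1.09 against control, where the 18 genes had a median of 2.39, but these were picked for large differences and 1 of them (C920009B18Rik) exceeded the upper quartile of the markers in a one-sided moderated test adjusted over all genes. A graded response to the siRNA procedure, which may be stronger in one group of mice, cannot be told apart from an effect of the Baf53b sequence, since 17 of the 18 genes were also higher in scrambled siRNA than control (median 0.43; 11 genes and a median of 0.19 under quantile normalization; the comparisons share the scrambled siRNA libraries) and the design holds 1 siRNA of each kind. An effect of Actl6b loss stays open and untested.

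The second pattern is that Actl6b was no lower beyond its error in the libraries labelled Baf53b siRNA. A higher share of neurons that hides a fall is argued against by 54 neuron markers with a median log2 difference of -0.12 (quartiles -0.16 and -0.04). The Actl6b difference of -0.09 lay between these quartiles, so Actl6b did not stand out from the neuron markers. Labels exchanged between Baf53b siRNA and scrambled siRNA cannot be told apart from labels as given, since Actl6b was not detectably lower in either siRNA group (lower end of the 95% interval against control -0.28 in scrambled siRNA and -0.37 in Baf53b siRNA). A fall in a small part of the dissected tissue, or at another time, cannot be told apart from no fall in whole tissue, where the lower end of the interval against scrambled siRNA was -0.38.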
